A study of Mus musculus with 8 samples.

How the data were processed

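Transcript levels were measured in 8 Smart-seq libraries of C57BL/6 mouse embryos, 2 per group (2C, 8C, CX22 and CX45), sequenced on a BGISEQ500 machine. Per the labels, total RNA was used, cDNA was amplified with KAPA HiFi polymerase, and libraries were made with Nextera XT. Per the labels, the authors aligned reads to the mouse genome build mm9 with HISAT2, listed with version 4.8.2, and quantified transcripts with Cufflinks 2.2.1. The settings, the annotation release and the read type are not given in the sources used here. The deposited table gave values in FPKM, made by the authors, with 1 value per RefSeq transcript and locus in each library. Replicates were not pooled by the authors. Reads were not reprocessed here.

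The table held 41876 transcript entries, of which 41685 matched a gene symbol of the reference annotation and 191 did not, the latter carrying between 0.065% and 0.253% of the summed FPKM of a library. FPKM of all entries of a gene were summed, which gave 24921 genes. The accessions listed at more than 1 locus, 337 in number, were summed too, so genes with near-identical copies are uncertain. Coordinates were read as starting at 0 and are printed from 1: for 2246 genes with a single entry the end minus the start equalled the transcript length, against 56 for which it was 1 short. Low FPKM values rise in steps set by transcript length and depth, and the implied depth of each library was taken as the number of fragments at which those steps became whole. Between 56.8% and 60.6% of the values checked lay within 0.05 of a whole number of fragments. These depths carry counting error only, and amplified cDNA without molecular identifiers does not give independent molecules.

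Genes at 1 FPKM or more in at least 2 of the 8 libraries were kept, which left 11873. Values were log2(FPKM + 1). The 2C libraries were checked for sampling noise: over 406 genes the chi-square of their difference was 0.9 times the chance median, and 5.7% of genes lay beyond the 95% point of chance. In the other groups the ratios were 28.18 (8C), 80.61 (CX22) and 40.0 (CX45). Over the same genes the mean chi-square was 2.46 in 2C, and 7 of all genes stood above 10 FPKM in one 2C library and at 0 in the other, so single genes differed by more than sampling noise. The 2C libraries were averaged and counted as 1 sample, which left 7 samples and 3 residual degrees of freedom. The lone 2C sample was assumed to vary like the other groups. The design had been written with 8 separate libraries, and that version was kept as an added alternative. All 4 groups were fitted together with limma 3.58.1 in R 4.3.3, with moderation that follows a trend on mean expression. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested and an absolute log2 fold change of at least 1. All 6 pairs of groups were compared, since the labels name no control, and the tests were two-sided.

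Before the data were examined, the comparisons, the test, 21 gene lists, the rule for named genes and the alternatives were fixed. The lists covered transient 2-cell-stage activation genes, maternal oocyte transcripts, pluripotency and inner cell mass genes, trophectoderm and epithelial genes, the machineries of RNA polymerases I, II and III, ribosome biogenesis factors, cytosolic ribosomal proteins, p53 targets, integrated stress response genes, chromatin architecture proteins, and DNA methylation and demethylation genes. They also covered S-phase genes, G2 and mitosis genes, glycolysis enzymes, oxidative phosphorylation subunits, proteasome subunits, and markers of cumulus cells, sperm and blood. Rps27l stood in both the ribosomal protein and the p53 lists. Each list was compared with the other genes tested by camera, with a preset correlation of 0.01 between genes, two-sided, adjusted over the 21 lists within a comparison. Camera with an estimated correlation was run beside it, and no list call in any of the 6 comparisons held there. Fry, which asks whether a list's genes move on balance one way, was run as an alternative. Named genes were, per comparison, the 6 called genes with the highest and the 6 with the lowest log2 fold change with a mean of at least 10 FPKM in the higher group, groups that did not overlap, and symbols that were not predicted or clone names. To these were added up to 4 members per list with the smallest p, and a fixed set (Polr1a, Polr1b, Rrn3, Ubtf, Fbl, Ncl, Zscan4d, Zfp352, Pou5f1, Nanog, Cdx2, Cdkn1a and Mdm2). Genes outside this rule are said to have been chosen after their values were seen.

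The fit was tested on simulated data in which 200 genes were changed by known amounts. Per comparison, 44% to 80% of genes changed by 3 on the log2 scale were recovered, and 2% to 14% of those at 1.5. Smaller changes went mostly uncalled. In each, 4 to 10 unchanged genes were called, and 0 changed genes took the wrong direction. These rates need not hold in the data, where 79 to 4906 genes were called.

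The position of a CX library between the stages was its projection on the difference of 1 2C and 1 8C library, over genes that differed by at least 2 on the log2 scale between the other 2C and 8C libraries. For comparisons sharing a group, correlation and covariance were set beside 100 simulations of groups without changes against the same samples. Alternatives were a pseudocount of 0.1, no filter or a filter at 5 FPKM, median-ratio rescaling, quantile normalization, a term for the replicate number, fits of only the compared groups, no trend, and each library left out in turn. Chosen after seeing the data were the most abundant entry per gene in place of the sum, and leaving out genes listed at 0 in a whole group. Averaging 2C in place of the 8 planned libraries was chosen after the noise check. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. No measurement other than these 8 libraries was analysed here.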

Results

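RNA of C57BL/6 mouse embryos was measured in 8 libraries made by Smart-seq, which copies and amplifies full-length cDNA from very small amounts of RNA. The labels sorted the libraries into 4 groups of 2, 2C, 8C, CX22 and CX45. The names 2C and 8C were read as the 2-cell and 8-cell stages. The labels spelled out neither CX22 nor CX45 and named no group as the control of another, so each of the 6 pairs of groups was compared. The series title concerned transcription by RNA polymerase I and chromatin architecture in embryos. Expression was given as FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library). In all, 11873 genes were tested. The depth implied by the steps between low values was 12.01 and 12.83 M fragments (M, 1e6) in the 2C libraries, 17.88 and 20.28 in 8C, 9.79 and 12.09 in CX22, and 11.02 and 12.69 in CX45. At those depths 3 fragments on a transcript of 2 kb came to between 0.074 and 0.153 FPKM, a limit that covers counting error only.

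For the median gene the 2C libraries differed by about sampling noise, with a chi-square ratio of 0.9 against 28.18 in 8C, 80.61 in CX22 and 40.0 in CX45. Single genes differed by more, with a mean chi-square of 2.46 in 2C and 7 genes above 10 FPKM in one 2C library and at 0 in the other. The 2C libraries may be 1 cDNA sequenced more than once, which the labels do not settle. They were counted as 1 sample, which gave 4400 calls in 8C against 2C, against 6697 with separate libraries, and values for 2C are means of both libraries without an SD. Values for the other groups are mean ± SD (n = 2), and a gene listed at 0 in a library is given library by library. The replicate correlation across genes, which are not independent replicates, was 0.996 in 2C, 0.98 in 8C, 0.871 in CX22 and 0.952 in CX45. In CX22, 333 genes stood above 10 FPKM in one library and at 0 in the other, against 16 in 8C and 48 in CX45. With 2 replicates the p-values measure only the spread between these samples, which may be technical. The words rose, fell and changed are kept for genes that passed the limma test. They describe listed values, and a listed 0 need not mean that a transcript was absent, since the table gives no read counts and an estimate may have failed. Gapdh, which nearly all cells express and which was chosen after its values were seen, was listed at 0 in 4 of the 8 libraries and at no more than 0.5187 FPKM in the others. Genes listed at 0 in a whole group made up 300 of 462 calls in CX22 against 2C, 39 of 79 in CX45 against 8C, and 876 of 4400 in 8C against 2C. Genes named in brackets after a count of 5 or fewer were chosen after their values were seen.

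Between 2C and 8C, many genes of the ribosome, its assembly factors, the proteasome and the respiratory chain rose, and many oocyte transcripts fell. Of 78 tested cytosolic ribosomal protein genes, 73 rose, and Rps6 went from 22.4 FPKM in 2C to 1864 ± 42.8 FPKM in 8C (log2 fold change 6.32). Of 43 maternal oocyte transcripts, 30 fell, and Oosp1 went from 1697 FPKM to 7.58 ± 2.93 FPKM (log2 fold change -7.67). Of 18 genes of the RNA polymerase I machinery, 8 rose, among them the initiation factor gene Rrn3. Across all genes limma called 4400, of which 1940 rose and 2460 fell.

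Cytosolic ribosomal proteins form the translating particle itself, and the list gave 73 risen and 1 fallen (Rps27l), or 76 and 1 when adjusted over the list alone. The median log2 fold change was 4.48, with camera adjusted p = 6.72e-29, adjusted p = 0.156 with an estimated correlation. The fallen gene, Rps27l, also belongs to the list of p53 targets and dropped from 9189 FPKM to 2248 ± 302 FPKM. Rpl5 rose from 9.82 FPKM to 951 ± 97.9 FPKM (log2 6.46). Ribosomal protein genes have many processed pseudogenes, so their exact levels are uncertain. Ribosome biogenesis factors process ribosomal RNA and assemble it with these proteins, and of 109 tested factors 67 rose and 1 fell (Nol8), or 73 and 1 when adjusted over the list alone (median 2.49, camera adjusted p = 1.48e-16, adjusted p = 0.129 with an estimated correlation). The snoRNP protein gene Fbl (chromosome 7, 28954767 to 28964288 in mm9, counted from 1) rose from 3.74 FPKM to 71.1 ± 2.73 FPKM (log2 3.93), and the nucleolin gene Ncl (chromosome 1, 88241294 to 88256030) from 13.7 FPKM to 122 ± 6.2 FPKM (log2 3.06). Nop58 rose by 3.49 and Nop16 by 4.82 on the log2 scale.

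RNA polymerase I transcribes the ribosomal RNA genes, and of its 18 tested machinery genes 8 rose and 10 were not called, with 10 risen when adjusted over the list alone. The median was 1.78, with camera adjusted p = 0.000121, adjusted p = 0.162 with an estimated correlation. Rrn3 (chromosome 16, 13780792 to 13814934), which carries the polymerase to the promoter, rose from 44.6 FPKM to 342 ± 16.8 FPKM (log2 2.91). The subunit gene Polr1b (chromosome 2, 128926732 to 128952331) rose from 2.62 FPKM to 16.2 ± 2.84 FPKM (log2 2.24). Ubtf, whose protein binds along ribosomal DNA, went from 0.192 FPKM to 28.9 ± 6.24 FPKM (log2 4.63). The largest subunit gene, Polr1a, was higher in 8C without passing limma (0.389 FPKM to 6.71 ± 1.61 FPKM, adjusted p = 0.0614). Znrd1 (log2 4.67) and Polr1c (log2 3.24) also rose. RNA polymerase II subunits, 13 in number, gave 5 risen (Polr2b, Polr2m, Polr2e, Polr2h and Polr2l) and 1 fallen (Polr2g), or 5 and 1 when adjusted over the list alone (median 1.23, camera adjusted p = 0.0567). Without CX22 replicate 1 or 2 camera passed for them at adjusted p = 0.0294 and 0.029 (0.00465 to 0.387 over all alternatives). RNA polymerase III machinery, 21 genes, gave 6 risen and 15 not called, with 6 risen when adjusted over the list alone (median 0.60, camera adjusted p = 0.112). Polr2h rose by 4.71 and Crcp by 2.75 on the log2 scale.

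Proteasome subunits make up the main protease of the cytosol, and of 36 tested genes 27 rose and 2 fell (Psme3 and Psme4), or 30 and 2 when adjusted over the list alone (median 3.15, camera adjusted p = 6.69e-10, adjusted p = 0.129 with an estimated correlation). Psma3 rose from 43.6 FPKM to 512 ± 17 FPKM and Psmb4 from 20.02 FPKM to 537 ± 12.2 FPKM. Of 77 oxidative phosphorylation subunits 39 rose and 1 fell (Ndufab1), or 41 and 1 when adjusted over the list alone (median 2.09, camera adjusted p = 3.49e-09, adjusted p = 0.162 with an estimated correlation), with Ndufa8 rising from 0.6499 FPKM to 146 ± 26.4 FPKM and Uqcrb from 32.4 FPKM to 628 ± 171 FPKM. Glycolysis enzymes, 19 genes, gave 3 risen (Hk1, Hk2 and Pfkfb3) and 3 fallen (Pfkp, Eno1 and Ldhb), or 3 and 4 when adjusted over the list alone (median 0.59, camera adjusted p = 0.721). Ldhb fell from 386 FPKM to 15.4 ± 6.06 FPKM.

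Maternal oocyte transcripts are stored during oocyte growth, and of 43 tested 1 rose (Ubtfl1) and 30 fell, or 1 and 32 when adjusted over the list alone (median -4.13, camera adjusted p = 1.61e-08, adjusted p = 0.264 with an estimated correlation). Omt2a fell from 31880 FPKM to 48.1 ± 3.63 FPKM (log2 -9.34), a level uncertain because its paralog Omt2b is nearly identical. Fbxw24 fell from 625 FPKM to 16.6 ± 3.33 FPKM. Transient 2-cell-stage activation genes are switched on for a short time when the embryonic genome is first transcribed, and of 33 tested 3 rose (Pramel6, Pramel7 and Obox6) and 12 fell, or 3 and 14 when adjusted over the list alone (median -3.00, camera adjusted p = 0.0111, adjusted p = 0.553 with an estimated correlation). Zscan4d stood at 67.3 FPKM in 2C and was listed at 0 and 0.817 FPKM in the 8C libraries (log2 -5.66), and Zfp352 (chromosome 4, 89885511 to 89892378) fell from 126 FPKM to 1.39 ± 0.665 FPKM (log2 -5.76). The Zscan4 genes are near-identical copies, so the split of fragments among them is uncertain.

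Pluripotency and inner cell mass genes, 33 tested, gave 12 risen and 3 fallen (Sox2, Tcl1 and Etv5), or 16 and 4 when adjusted over the list alone (median 1.62, camera adjusted p = 0.0094, adjusted p = 0.162 with an estimated correlation). Nanog rose from 0.1297 FPKM to 19.2 ± 1.42 FPKM (log2 4.16), Dppa2 from 15.4 FPKM to 733 ± 139 FPKM and Dppa4 from 48.01 FPKM to 659 ± 88.7 FPKM, while Tcl1 fell from 1794 FPKM to 17.1 ± 7.45 FPKM. Pou5f1, listed at 0.252 and 0 FPKM in the 2C libraries and at 12 ± 5.96 FPKM in 8C, did not pass limma (adjusted p = 0.0672). Trophectoderm and epithelial genes, 34 tested, gave 9 risen and 1 fallen (Ezr), or 7 and 1 when adjusted over the list alone (median 0.33, camera adjusted p = 0.143). Cdx2 was not among the tested genes. F11r rose from 4.33 FPKM to 70.9 ± 14.9 FPKM. Tead4 rose to 22.1 ± 2.88 FPKM in 8C and was listed at 0 in both 2C libraries.

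S-phase and replication genes, 48 tested, gave 15 risen and 5 fallen (Rfc5, Rpa3, Orc2, Ccne2 and Slbp), or 16 and 5 when adjusted over the list alone (median 1.18, camera adjusted p = 0.00251, adjusted p = 0.174 with an estimated correlation), with Rpa2 rising by 4.32 and Gins1 by 3.98 on the log2 scale. G2 and mitosis genes, 45 tested, gave 9 risen and 9 fallen, or 10 and 9 when adjusted over the list alone (median 0.52, camera adjusted p = 0.437). Ccnb1 rose to 1815 ± 304 FPKM while Pttg1 fell to 562 ± 85.5 FPKM. Chromatin architecture proteins, 54 tested, gave 11 risen and 9 fallen, or 7 and 5 when adjusted over the list alone, with a median of 0.27 and a mean of -0.03, which differ in sign (camera adjusted p = 0.639). Wapl, which releases cohesin from DNA, fell from 503 FPKM to 50.7 ± 15 FPKM, Ncapg2 fell by 3.11 on the log2 scale, and Hmgb1 rose by 2.97. DNA methylation and demethylation genes, 19 tested, gave 2 risen (Tet1 and Mbd4) and 2 fallen (Uhrf1 and Tet3), or 0 and 1 when adjusted over the list alone (median -0.57, camera adjusted p = 0.662), Uhrf1 going from 19.1 FPKM to 2.17 ± 0.83 FPKM and Tet1 from 0.659 FPKM to 4.19 ± 0.396 FPKM.

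Among 33 p53 target genes 5 rose (Cdkn1a, Bax, Aen, Perp and Tigar) and 8 fell, or 5 and 8 when adjusted over the list alone (median -0.28, camera adjusted p = 0.769). Quantile normalization turned the median to 0.22. Cdkn1a rose from 11.9 FPKM to 72.8 ± 6.47 FPKM, Trp53inp1 fell from 60.6 FPKM to 5.08 ± 2.4 FPKM, and Mdm2 (24.5 FPKM and 10.7 ± 2.12 FPKM) did not pass limma (adjusted p = 0.0587). Integrated stress response genes, 23 tested, gave 6 risen and 4 fallen (Shmt2, Mthfd2, Slc7a11 and Stc2), or 7 and 4 when adjusted over the list alone (median 0.92, camera adjusted p = 0.301). Mthfd2 fell from 129 FPKM to 5.37 ± 0.393 FPKM. Among 6 cumulus and granulosa cell markers 2 fell (Star and Adamts1) and 4 were not called, with 2 fallen when adjusted over the list alone (median -1.37, camera adjusted p = 0.305). Camera passed without CX22 replicate 1 (adjusted p = 0.0343) or 2 (0.0497, 0.0105 to 0.496 over all alternatives). The 6 sperm transcripts gave 0 genes called by limma, also when adjusted over the list alone, with 0 higher and 0 lower at an unadjusted p under 0.05 (median -1.82, camera adjusted p = 0.412). The 6 blood and immune cell markers gave 0 genes called by limma, also when adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05 (median -0.86, camera adjusted p = 0.412).

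The genes with the largest rise at 10 FPKM or more included Snrpb (0.498 FPKM to 649 ± 205 FPKM) and Mrpl20 (0.0712 FPKM to 379 ± 24.3 FPKM). Ak6 (670.5 ± 14.4 FPKM in 8C), Rbis (555 ± 174 FPKM) and Oaz1-ps (511 ± 124 FPKM) were listed at 0 in both 2C libraries, and Znrd2 (355 ± 28.8 FPKM in 8C) in 1 of them. Oaz1-ps is annotated as a pseudogene, so its level is uncertain. The largest falls were those of AA545190 (4219 FPKM to 1.93 ± 2.19 FPKM), D16Ertd519e (569.7 FPKM in 2C, listed at 0 and 0.162 FPKM in the 8C libraries), Oosp3, Oosp2 and Ifitm3. Since 2C counts as 1 sample, the spread came from the replicates of 8C, CX22 and CX45 together. The call count was 1490 without 8C replicate 1, 1417 without 8C replicate 2, 5622 and 5608 without CX22 replicate 1 and 2, and 3812 and 3817 without CX45 replicate 1 and 2. Of 92 called genes followed, 38 lost their call without 8C replicate 1 and 41 without 8C replicate 2, among them in both settings Polr1b, Ubtf, Ncl, Zfp352, Cdkn1a, Rps27l, F11r, Crcp, Uhrf1 and Tet1. Without CX45 replicate 1 or 2, 17 and 18 were lost (Polr1b and Tet1 among them), 4 without either CX22 library (Zfp352 among them), and 1 without either 2C library.

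CX22 stood closer to 2C than to 8C. The CX22 libraries correlated with the 2C libraries at 0.874 to 0.899 across genes, with the 8C libraries at 0.662 to 0.678, and with each other at 0.871. Limma called 462 genes, of which 71 rose and 391 fell, against 4906 between CX22 and 8C. Of the 21 lists only the cytosolic ribosomal proteins passed camera, with a median of 0.29.

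Ribosomal protein genes gave 3 risen (Rpl5, Rps6 and Rps15) and 75 not called, with 3 risen when adjusted over the list alone (camera adjusted p = 2.45e-05, adjusted p = 0.708 with an estimated correlation). Rps6 rose from 22.4 FPKM to 97.7 ± 14.1 FPKM (log2 2.07), Rpl5 from 9.82 FPKM to 35.2 ± 1.16 FPKM and Rps15 from 32.95 FPKM to 123 ± 4.27 FPKM. Without CX22 replicate 1 the list's median was 0.05 and camera gave adjusted p = 0.29 (5.51e-08 to 0.708 over all alternatives). In 8C the same genes stood at 1864 ± 42.8 FPKM, 951 ± 97.9 FPKM and 2887 ± 56.6 FPKM. Ribosome biogenesis factors gave 1 risen (Rrp1) and 108 not called, with 0 risen when adjusted over the list alone (median -0.03, camera adjusted p = 0.184), while the list passed camera without CX22 replicate 2 (adjusted p = 0.00908, 0.00908 to 0.972 over all alternatives). Rrp1 rose from 0.181 FPKM to 4.22 ± 0.204 FPKM. RNA polymerase I machinery gave 0 genes called by limma, also when adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 (median 0.33, camera adjusted p = 0.588). Rrn3 stood at 34.9 ± 9.89 FPKM in CX22 and 44.6 FPKM in 2C (limma adjusted p = 0.726). Polr1a, Polr1b, Ubtf, Fbl and Ncl were not called either. RNA polymerase II subunits gave 0 genes called by limma, also when adjusted over the list alone, with 1 higher and 0 lower at an unadjusted p under 0.05 (median -0.03). RNA polymerase III machinery gave 0 genes called by limma, also when adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05 (median -0.36). Proteasome subunits gave 1 fallen (Psma4) and 35 not called, with 1 fallen when adjusted over the list alone (median -0.27). Oxidative phosphorylation subunits gave 0 genes called by limma, also when adjusted over the list alone, with 4 higher and 6 lower at an unadjusted p under 0.05 (median -0.23). Psma4 fell from 39.3 FPKM to 8.61 ± 1.94 FPKM.

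Maternal oocyte transcripts gave 0 genes called by limma, also when adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 (median -0.22). Transient 2-cell-stage activation genes gave 0 genes called by limma, also when adjusted over the list alone, with 0 higher and 2 lower at an unadjusted p under 0.05 (median 0.16 and mean -0.03, which differ in sign). Zscan4d stood at 67.3 FPKM in 2C and 128 ± 29.3 FPKM in CX22 (limma adjusted p = 0.67), and Zfp352 at 126 FPKM and 105 ± 11.8 FPKM (limma adjusted p = 1). Pluripotency genes gave 1 fallen (Sox2) and 32 not called, with 1 fallen when adjusted over the list alone, and Sox2 fell from 4.25 FPKM to 0.404 ± 0.0441 FPKM. Trophectoderm genes gave 0 genes called by limma, also when adjusted over the list alone, with 2 higher and 3 lower at an unadjusted p under 0.05. DNA methylation genes gave 0 genes called by limma, 1 higher and 0 lower when adjusted over the list alone, and 2 higher and 0 lower at an unadjusted p under 0.05. The medians of these 3 lists, -0.03, -0.08 and -0.25, lay opposite to the direction of the camera test, as did those of the maternal transcripts, the ribosome biogenesis factors, the RNA polymerase II and oxidative phosphorylation subunits, and the blood markers. S-phase genes gave 0 genes called by limma, also when adjusted over the list alone, with 2 higher and 4 lower at an unadjusted p under 0.05 (median 0.14). G2 and mitosis genes gave 0 genes called by limma, also when adjusted over the list alone, with 1 higher and 2 lower at an unadjusted p under 0.05 (median 0.05 and mean -0.01). Chromatin architecture proteins gave 0 genes called by limma, also when adjusted over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05 (median 0.17). Among p53 targets 1 fell (Fas) and 32 were not called, with 1 fallen when adjusted over the list alone (median -0.03), among integrated stress response genes 1 fell (Stc2) and 22 were not called, with 1 risen and 1 fallen when adjusted over the list alone (median 0.46), and among glycolysis enzymes 1 fell (Eno1) and 18 were not called, with 1 fallen when adjusted over the list alone (median 0.06). Fas, Stc2 and Eno1 were listed at 0 in both CX22 libraries, against 5.95 FPKM, 1.89 FPKM and 1.84 FPKM in 2C. Cumulus markers gave 1 fallen (Star) and 5 not called, with 2 fallen when adjusted over the list alone (median -0.35). Sperm transcripts gave 0 genes called by limma, also when adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05 (median -1.17). Blood markers gave 0 genes called by limma, 2 higher and 1 lower when adjusted over the list alone, and 2 higher and 1 lower at an unadjusted p under 0.05 (median -0.51 and mean 0.05, which differ in sign). Camera adjusted p lay between 0.145 and 0.917 for the lists other than the ribosomal proteins.

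The calls with the largest fold changes were mostly genes listed at 0 in one group, where the 0 may be a failed estimate, and such genes made up 300 of the 462 calls. Diablo, whose protein promotes apoptosis, stood at 30.98 ± 9.03 FPKM in CX22 and was listed at 0 in both 2C libraries, as were Oip5 (23.96 ± 2.16 FPKM) and Shoc2 (22.4 ± 4.55 FPKM). Isy1 rose from 0.0497 FPKM to 18.3 ± 1.49 FPKM. Dnajc19 stood at 41.6 FPKM in 2C and was listed at 0 in both CX22 libraries, as were Ethe1 (27.8 FPKM in 2C), Cypt2 (28.2 FPKM) and Rpain (24.5 FPKM). The call count was 229 without 8C replicate 1, 223 without 8C replicate 2 and 1113 without CX22 replicate 2. Of 22 called genes followed, 16 lost their call without 8C replicate 1 or 2 and 7 without CX45 replicate 1 or 2, Rps6, Rpl5, Rrp1 and Psma4 in each of these settings. Without CX22 replicate 1, 6 were lost (Rps15, Sox2 and Oip5 among them), without CX22 replicate 2, 3 (Sox2 among them), and without 2C replicate 2, 1 (Eno1).

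Between 8C and CX22, limma called 4906 genes, of which 2360 rose and 2546 fell. Of 78 ribosomal protein genes 76 fell, as did 76 of 109 ribosome biogenesis factors and 31 of 36 proteasome subunits. Of 43 maternal transcripts 29 rose, as did 17 of 33 2-cell-stage activation genes.

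Of the ribosomal protein genes 1 rose (Rps27l) and 76 fell, or 1 and 77 when adjusted over the list alone (median -4.16, camera adjusted p = 3.33e-25, adjusted p = 0.187 with an estimated correlation). Rps9 fell from 2223 ± 246 FPKM in 8C to 74.6 ± 1.85 FPKM in CX22. Ribosome biogenesis factors gave 1 risen (Nol8) and 76 fallen, or 1 and 85 when adjusted over the list alone (median -2.42, camera adjusted p = 9.49e-16, adjusted p = 0.136 with an estimated correlation), with Fbl at 71.1 ± 2.73 FPKM and 2.53 ± 0.958 FPKM. RNA polymerase I machinery gave 11 fallen and 7 not called, with 12 fallen when adjusted over the list alone (median -1.87, camera adjusted p = 0.000786, adjusted p = 0.199 with an estimated correlation). Rrn3 fell from 342 ± 16.8 FPKM to 34.9 ± 9.89 FPKM (log2 -3.28), Polr1b from 16.2 ± 2.84 FPKM to 0.603 ± 0.491 FPKM (log2 -3.45) and Polr1c from 212 ± 61 FPKM to 18.5 ± 0.347 FPKM. RNA polymerase III machinery gave 9 fallen and 12 not called, with 10 fallen when adjusted over the list alone (median -1.34, camera adjusted p = 0.0348, adjusted p = 0.199 with an estimated correlation). Camera gave 0.0549 without 8C replicate 2, 0.0505 without CX22 replicate 2, 0.0505 without CX45 replicate 1 and 0.0502 without CX45 replicate 2 (0.00127 to 0.199 over all alternatives). Proteasome subunits gave 1 risen (Psme4) and 31 fallen, or 2 and 31 when adjusted over the list alone (median -4.00, camera adjusted p = 1.04e-09, adjusted p = 0.136 with an estimated correlation). Oxidative phosphorylation subunits gave 4 risen (Ndufa11, Ndufab1, Sdha and Cox7b) and 43 fallen, or 5 and 49 when adjusted over the list alone (median -2.36, camera adjusted p = 1.28e-08, adjusted p = 0.199 with an estimated correlation). S-phase genes gave 3 risen (Rpa3, Orc2 and Ccne2) and 18 fallen, or 3 and 18 when adjusted over the list alone (median -1.26, camera adjusted p = 0.00718, adjusted p = 0.199 with an estimated correlation). Psma4 stood at 8.61 ± 1.94 FPKM in CX22 against 343 ± 1.99 FPKM in 8C, and Tyms at 1.56 ± 0.191 FPKM against 72.9 ± 9.0 FPKM.

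Maternal transcripts gave 29 risen and 1 fallen (Padi6), or 31 and 2 when adjusted over the list alone (median 3.65, camera adjusted p = 4.69e-10, adjusted p = 0.235 with an estimated correlation). The 2-cell-stage activation genes gave 17 risen and 3 fallen (Pramel6, Pramel7 and Obox6), or 17 and 3 when adjusted over the list alone (median 2.94, camera adjusted p = 0.00162, adjusted p = 0.467 with an estimated correlation). Omt2a stood at 37140 ± 4630 FPKM in CX22 against 48.1 ± 3.63 FPKM in 8C, and Oosp1 at 1486 ± 309 FPKM against 7.58 ± 2.93 FPKM. Pluripotency genes gave 1 risen (Tcl1) and 15 fallen, or 3 and 15 when adjusted over the list alone (median -1.41, camera adjusted p = 0.037, adjusted p = 0.199 with an estimated correlation), Nanog falling from 19.2 ± 1.42 FPKM to 0.257 ± 0.071 FPKM and Dppa2 from 733 ± 139 FPKM to 23.9 ± 2.02 FPKM. Camera for that list gave 0.0508 without 8C replicate 2, 0.0508 without CX22 replicate 1, 0.127 without CX22 replicate 2, 0.0505 without CX45 replicate 1 and 0.0502 without CX45 replicate 2 (0.000998 to 0.199 over all alternatives). Among p53 targets 8 rose and 8 fell, or 8 and 8 when adjusted over the list alone (median -0.39 and mean 0.01, which differ in sign), with Mdm2 higher in CX22 (log2 2.12) and Cdkn1a lower (-2.24). Glycolysis enzymes had a median of -0.27 and a mean of 0.03. The lists other than those with a camera call did not pass, with camera adjusted p between 0.139 and 0.977. The call count was 1921 without 8C replicate 1 and 1871 without 8C replicate 2. Of 53 called genes followed, 13 lost their call without 8C replicate 1 (Polr1b and Cdkn1a among them) and 15 without 8C replicate 2 (Cdkn1a among them). Without CX22 replicate 1 or 2, 7 and 5 were lost, and 5 without either CX45 library.

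CX45 stood closer to 8C than to 2C, its libraries correlating across genes with those of 8C at 0.927 to 0.933 and with those of 2C at 0.752 to 0.771. Limma called 79 genes, of which 55 rose and 24 fell, with 2286 at an unadjusted p under 0.05. Among the risen genes were the p53 targets Mdm2 and Trp53inp1 and the maternal transcripts Omt2a and Fbxw24. Of the ribosomal protein, proteasome and RNA polymerase I lists, which held many risen genes between 2C and 8C, limma called 0 genes here, with 1 higher and 35 lower, 1 higher and 4 lower, and 1 higher at an unadjusted p under 0.05. The calls did not hold under most alternatives. Limma called 0 genes without a filter, after median-ratio rescaling, after quantile normalization and with the replicate term, and all 19 called genes followed were lost in each, with between 1809 and 2700 genes at an unadjusted p under 0.05. The log2 fold change of Mdm2 was 3.19 (SE 0.282, adjusted p = 0.0443), against 2.705 (SE 0.291, 0.0675) and 2.718 (SE 0.317, 0.0592) under the 2 scalings. Trp53inp1 went from 3.71 (SE 0.346, adjusted p = 0.0458) to 3.234 (SE 0.346, 0.0675) and 3.174 (SE 0.365, 0.0592). Both genes share the adjusted p there, which depends on the ranks of the other genes too, and the cause of the lost calls was not tested. Nor was any gene called by limma when any 1 library of 8C, CX22 or CX45 was left out, with between 1238 and 3218 genes at an unadjusted p under 0.05.

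The median over all genes was 0.31 above 0 in this comparison, 0.33 against 2C and 0.47 against CX22, while median-ratio rescaling took these medians to 0.01, -0.05 and 0.13 and quantile normalization to 0.00, 0.12 and 0.06. List medians in the CX45 comparisons are therefore also given after subtracting the median of all genes (relative). Among 33 p53 targets 2 rose (Mdm2 and Trp53inp1) and 31 were not called, with 10 risen when adjusted over the list alone (median 0.85, relative 0.55, camera adjusted p = 0.000282, adjusted p = 0.396 with an estimated correlation). Mdm2 (chromosome 10, 117125931 to 117147814), which encodes the ubiquitin ligase of p53, rose from 10.7 ± 2.12 FPKM in 8C to 106 ± 24.7 FPKM in CX45 (log2 3.19), against 24.5 FPKM in 2C. Trp53inp1 (chromosome 4, 11083588 to 11101526) rose from 5.08 ± 2.4 FPKM to 75.3 ± 5.03 FPKM (log2 3.71), with 60.6 FPKM in 2C. Btg2 (0.2602 ± 0.265 FPKM and 16.7 ± 6.63 FPKM) missed the limma threshold at adjusted p = 0.0586 and Ercc5 (2.01 ± 0.292 FPKM and 36.4 ± 17.9 FPKM) at 0.0683. Cdkn1a was 72.8 ± 6.47 FPKM and 139 ± 29.3 FPKM (adjusted p = 0.232).

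Maternal transcripts gave 2 risen (Omt2a and Fbxw24) and 41 not called, with 9 risen when adjusted over the list alone (median 1.34, relative 1.04, camera adjusted p = 1.61e-05, adjusted p = 0.396 with an estimated correlation). Omt2a rose from 48.1 ± 3.63 FPKM to 694 ± 162 FPKM and Fbxw24 (chromosome 9, 109503630 to 109528573) from 16.6 ± 3.33 FPKM to 101 ± 23.8 FPKM. In 2C they stood at 31880 FPKM and 625 FPKM. The 2-cell-stage activation genes gave 0 genes called by limma, 9 higher and 0 lower when adjusted over the list alone, and 19 higher and 1 lower at an unadjusted p under 0.05 (median 2.21, relative 1.91, camera adjusted p = 6.35e-05, adjusted p = 0.396 with an estimated correlation). Spz1 was at 5.69 ± 0.531 FPKM in 8C and 63.9 ± 1.01 FPKM in CX45 (limma adjusted p = 0.0586). Zfp352 was at 20.9 FPKM in one CX45 library and 178.8 in the other, against 1.39 ± 0.665 FPKM in 8C.

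Ribosomal protein genes gave 0 genes called by limma, 0 higher and 1 lower when adjusted over the list alone, and 1 higher and 35 lower at an unadjusted p under 0.05 (median -0.70, relative -1.01, camera adjusted p = 1.57e-25, adjusted p = 0.141 with an estimated correlation). Rpl5 stood at 951 ± 97.9 FPKM in 8C and 332 ± 2.32 FPKM in CX45 (limma adjusted p = 0.0552), and Rps16 at 2900 ± 127 FPKM and 1505 ± 148 FPKM. Ribosome biogenesis factors gave 0 genes called by limma, also when adjusted over the list alone, with 3 higher and 6 lower at an unadjusted p under 0.05 (median -0.08, relative -0.39, camera adjusted p = 0.00339, adjusted p = 0.396 with an estimated correlation). Quantile normalization took that camera value to 0.0638 (9.5e-07 to 0.784 over all alternatives). Nop58 stood at 313 ± 16 FPKM and 125 ± 7.12 FPKM, and Fbl at 71.1 ± 2.73 FPKM and 48.3 ± 3.27 FPKM. RNA polymerase I machinery gave 0 genes called by limma, also when adjusted over the list alone, with 1 higher and 0 lower at an unadjusted p under 0.05, with a median of 0.06 (relative -0.25, -0.40 after median-ratio rescaling and -0.07 after quantile normalization) and a test directed downward (camera adjusted p = 0.437). Rrn3 was 342 ± 16.8 FPKM in 8C and 271 ± 9.56 FPKM in CX45, Polr1b 16.2 ± 2.84 FPKM and 14.4 ± 3.52 FPKM, and Ubtf 28.9 ± 6.24 FPKM and 16.03 ± 0.638 FPKM, none of them called. RNA polymerase II subunits gave 0 genes called by limma, also when adjusted over the list alone, with 2 higher and 0 lower at an unadjusted p under 0.05 (median 0.21, relative -0.10, -0.28 after median-ratio rescaling and 0.21 after quantile normalization, with a test directed downward, camera adjusted p = 0.985). RNA polymerase III machinery gave 0 genes called by limma, 1 higher and 0 lower when adjusted over the list alone, and 5 higher and 0 lower at an unadjusted p under 0.05 (median 0.42, relative 0.11, -0.05 after median-ratio rescaling and 0.06 after quantile normalization, camera adjusted p = 0.437).

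Proteasome subunits gave 0 genes called by limma, 1 higher and 0 lower when adjusted over the list alone, and 1 higher and 4 lower at an unadjusted p under 0.05 (median -0.56, relative -0.87, camera adjusted p = 6.51e-06, adjusted p = 0.141 with an estimated correlation). Oxidative phosphorylation subunits gave 0 genes called by limma, also when adjusted over the list alone, with 7 higher and 3 lower at an unadjusted p under 0.05 (median -0.08, relative -0.39, camera adjusted p = 0.049, adjusted p = 0.516 with an estimated correlation). The direction turned upward under quantile normalization (camera 0.937) and fry (0.95). Without 8C replicate 1 or CX45 replicate 2 camera gave 0.478 and 0.318, with medians of 0.08 and 0.00 (9.75e-05 to 0.95 over all alternatives). S-phase genes gave 0 genes called by limma, also when adjusted over the list alone, with 3 higher and 2 lower at an unadjusted p under 0.05 (median -0.03, relative -0.33, camera adjusted p = 0.049, adjusted p = 0.396 with an estimated correlation). Camera gave 0.114 without 8C replicate 1, 0.0782 without 8C replicate 2 and 0.139 without CX45 replicate 1 (0.00254 to 0.868 over all alternatives). Pluripotency genes gave 0 genes called by limma, also when adjusted over the list alone, with 3 higher and 9 lower at an unadjusted p under 0.05 (median -0.76, relative -1.06, camera adjusted p = 6.35e-05, adjusted p = 0.141 with an estimated correlation), Nanog standing at 19.2 ± 1.42 FPKM and 5.53 ± 1.41 FPKM (limma adjusted p = 0.122). Trophectoderm genes gave 0 genes called by limma, also when adjusted over the list alone, with 1 higher and 6 lower at an unadjusted p under 0.05 (median -0.14, relative -0.45, camera adjusted p = 0.00129, adjusted p = 0.141 with an estimated correlation).

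Chromatin architecture proteins gave 2 risen (Rec8 and Setdb1) and 52 not called, with 6 risen and 2 fallen when adjusted over the list alone (median 0.37, relative 0.07, -0.08 after median-ratio rescaling and 0.01 after quantile normalization, camera adjusted p = 0.631). The histone methyltransferase gene Setdb1 was listed at 0 in 8C and stood at 13.1 ± 4.25 FPKM in CX45, and the meiotic cohesin gene Rec8 was listed at 0 in 8C and stood at 1.196 ± 0.12 FPKM. DNA methylation genes gave 0 genes called by limma, also when adjusted over the list alone, with 3 higher and 0 lower at an unadjusted p under 0.05 (median 0.58, relative 0.27, camera adjusted p = 0.543). G2 and mitosis genes gave 1 risen (Spc25) and 44 not called, with 4 risen when adjusted over the list alone (median 0.57, relative 0.26, camera adjusted p = 0.135). Camera passed after quantile normalization (0.0446, 0.0336 to 0.824 over all alternatives). The kinetochore gene Spc25 rose from 86.3 ± 29.2 FPKM to 826 ± 32.1 FPKM. Glycolysis enzymes gave 1 risen (Eno1) and 18 not called, with 2 risen and 2 fallen when adjusted over the list alone (median 0.19, relative -0.11, -0.07 after median-ratio rescaling and -0.06 after quantile normalization, camera adjusted p = 0.985). Integrated stress response genes gave 0 genes called by limma, 2 higher and 1 lower when adjusted over the list alone, and 4 higher and 1 lower at an unadjusted p under 0.05 (median 0.23, relative -0.08, -0.15 after median-ratio rescaling and -0.11 after quantile normalization, with a test directed downward, camera adjusted p = 0.985). Cumulus markers gave 0 genes called by limma, also when adjusted over the list alone, with 0 higher and 0 lower at an unadjusted p under 0.05 (median 0.03, relative -0.27, with a test directed downward, camera adjusted p = 0.568). Sperm transcripts gave 0 genes called by limma, also when adjusted over the list alone, with 2 higher and 0 lower at an unadjusted p under 0.05 (median 0.78, relative 0.47, camera adjusted p = 0.437). Blood markers gave 0 genes called by limma, 2 higher and 0 lower when adjusted over the list alone, and 2 higher and 0 lower at an unadjusted p under 0.05 (median 1.08, relative 0.78, camera adjusted p = 0.0592). Camera passed for the blood markers after median-ratio rescaling (0.0309), after quantile normalization (0.0446), with a filter at 5 FPKM (0.0298) and in a fit of only these groups (0.0317). It also passed without 8C replicate 2 (0.0326), CX22 replicate 1 (0.0469) or CX22 replicate 2 (0.0347, 0.0298 to 0.495 over all alternatives). Hba-a1, a globin gene with near-identical copies, stood at 19.5 ± 13 FPKM in 8C and 317 ± 43.1 FPKM in CX45 (limma adjusted p = 0.0815).

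Other risen genes were Nat8f2 (0.889 ± 0.0459 FPKM to 30.3 ± 4.01 FPKM), Pnrc1 (listed at 0 and 0.0512 FPKM in the 8C libraries, 18.4 ± 0.713 FPKM in CX45) and Ube3a (listed at 0 in 8C, 14.4 ± 4.41 FPKM in CX45). Mettl5 (chromosome 2, 69709252 to 69723672), which methylates 18S ribosomal RNA, stood at 91.3 ± 3.98 FPKM in 8C and was listed at 0 in both CX45 libraries, as were Exosc9 (46.5 ± 8.58 FPKM in 8C), an exosome subunit gene, Chpt1 (33.5 ± 9.5 FPKM) and Eif3j1 (13.6 ± 1.45 FPKM). Mettl5 and Exosc9 were listed at 0 in both 2C libraries too. The calls of these 4 genes rest on listed zeros, which may be failed estimates, while 31 of the 79 called genes had no listed 0 in any 8C or CX45 library (30 risen, 1 fallen).

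Against 2C, 71 of 78 ribosomal protein genes, 67 of 109 ribosome biogenesis factors and 22 of 36 proteasome subunits rose in CX45, and 24 of 43 maternal transcripts fell. Limma called 3536 genes, of which 1924 rose and 1612 fell. Of the called genes 54.4% were higher in CX45, a share that was 39.1% after median-ratio rescaling and 45.1% after quantile normalization.

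Ribosomal protein genes gave 71 risen and 1 fallen (Rps27l), or 72 and 1 when adjusted over the list alone (median 3.74, relative 3.41, camera adjusted p = 9.41e-24, adjusted p = 0.193 with an estimated correlation). Rps6 rose from 22.4 FPKM to 1075 ± 108 FPKM. Ribosome biogenesis factors gave 67 risen and 42 not called, with 72 risen when adjusted over the list alone (median 2.35, relative 2.02, camera adjusted p = 5.93e-15, adjusted p = 0.193 with an estimated correlation). Wdr74 rose from 0.964 FPKM to 226 ± 72 FPKM. RNA polymerase I machinery gave 9 risen and 9 not called, with 12 risen when adjusted over the list alone (median 2.36, relative 2.03, camera adjusted p = 0.000189, adjusted p = 0.193 with an estimated correlation), Rrn3 rising from 44.6 FPKM to 271 ± 9.56 FPKM (log2 2.58). RNA polymerase II subunits gave 5 risen (Polr2b, Polr2d, Polr2e, Polr2h and Polr2l) and 8 not called, with 6 risen when adjusted over the list alone (median 1.73, relative 1.40, camera adjusted p = 0.0493, adjusted p = 0.249 with an estimated correlation), a call lost under both scalings (0.133 and 0.193, 0.00445 to 0.249 over all alternatives). RNA polymerase III machinery gave 6 risen and 15 not called, with 6 risen when adjusted over the list alone (median 1.23, relative 0.89, camera adjusted p = 0.0157, adjusted p = 0.193 with an estimated correlation). Median-ratio rescaling took its camera value to 0.062 (0.00293 to 0.193 over all alternatives). Proteasome subunits gave 22 risen and 14 not called, with 25 risen when adjusted over the list alone (median 2.57, relative 2.24, camera adjusted p = 1.06e-07, adjusted p = 0.193 with an estimated correlation). Oxidative phosphorylation subunits gave 38 risen and 39 not called, with 39 risen and 1 fallen when adjusted over the list alone (median 1.97, relative 1.64, camera adjusted p = 2.22e-08, adjusted p = 0.193 with an estimated correlation). S-phase genes gave 12 risen and 36 not called, with 12 risen when adjusted over the list alone (median 1.40, relative 1.06, camera adjusted p = 0.0187, adjusted p = 0.249 with an estimated correlation). Their camera value was 0.055 after median-ratio rescaling (0.00445 to 0.249 over all alternatives). Camera for the RNA polymerase II subunits also gave 0.0512 without 2C replicate 2, 0.0705 and 0.0708 without 8C replicate 1 and 2, and 0.0919 and 0.0721 without CX45 replicate 1 and 2. Without CX22 replicate 1 or 2, camera passed for the G2 and mitosis genes (0.0445 and 0.0435, 0.00962 to 0.359 over all alternatives) and the cumulus markers (0.0126 and 0.0196, 0.00966 to 0.355 over all alternatives).

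Maternal transcripts gave 1 risen (Ubtfl1) and 24 fallen, or 1 and 27 when adjusted over the list alone (median -3.02, relative -3.35, camera adjusted p = 2.64e-08, adjusted p = 0.294 with an estimated correlation). Oosp1 fell from 1697 FPKM to 75.9 ± 18.5 FPKM. The 2-cell-stage activation genes gave 2 risen (Pramel7 and Obox6) and 1 fallen (Arg2), or 0 and 0 when adjusted over the list alone (median -0.43, relative -0.77, camera adjusted p = 0.531). Without CX45 replicate 2 camera passed downward at 0.00732 (0.00732 to 0.808 over all alternatives). Obox6 rose from 41.1 FPKM to 1260 ± 784 FPKM. Among p53 targets 9 rose and 3 fell (Fas, Rrm2b and Rps27l), or 9 and 3 when adjusted over the list alone (median 1.27, relative 0.94, camera adjusted p = 0.0804). Without CX45 replicate 1 camera passed at 0.0368 (0.0368 to 0.528 over all alternatives). Cdkn1a rose from 11.9 FPKM to 139 ± 29.3 FPKM and Mdm2 from 24.5 FPKM to 106 ± 24.7 FPKM, while Rrm2b fell to 13.5 ± 8.62 FPKM from 133 FPKM. DNA methylation genes (mean -0.18, relative median -0.26, and a median of 0.08 that was -0.42 after median-ratio rescaling and -0.02 after quantile normalization) and chromatin architecture proteins (0.36, -0.06 after median-ratio rescaling and 0.10 after quantile normalization) did not pass camera, nor did the lists not named above, with adjusted p between 0.0804 and 0.807. The call count was 1526 without 8C replicate 1, 1502 without 8C replicate 2, 1800 without CX45 replicate 1 and 2082 without CX45 replicate 2. Of 44 called genes followed, 14 lost their call without 8C replicate 1, 15 without 8C replicate 2, 12 without CX45 replicate 1 and 10 without CX45 replicate 2. Mdm2 was lost in all but the last, Obox6 in all but the one without CX45 replicate 1, and Rrm2b without either 8C library.

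CX45 and CX22 differed in 4326 genes called by limma, of which 2729 rose and 1597 fell from CX22 to CX45. Of the called genes 63.1% were higher in CX45, a share that was 50.2% after median-ratio rescaling and 49.2% after quantile normalization. Of 78 ribosomal protein genes 72 rose, as did 29 of 36 proteasome subunits, and 28 of 43 maternal transcripts fell.

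Ribosomal protein genes gave 72 risen and 1 fallen (Rps27l), or 76 and 1 when adjusted over the list alone (median 3.21, relative 2.74, camera adjusted p = 2.4e-20, adjusted p = 0.208 with an estimated correlation), Rpl31 rising from 43.5 ± 4.8 FPKM in CX22 to 712 ± 10.7 FPKM in CX45. Ribosome biogenesis factors gave 80 risen and 29 not called, with 89 risen when adjusted over the list alone (median 2.31, relative 1.84, camera adjusted p = 2.47e-14, adjusted p = 0.195 with an estimated correlation). RNA polymerase I machinery gave 10 risen and 8 not called, with 14 risen when adjusted over the list alone (median 2.28, relative 1.81, camera adjusted p = 0.000656, adjusted p = 0.208 with an estimated correlation). RNA polymerase III machinery gave 8 risen and 13 not called, with 11 risen when adjusted over the list alone (median 1.86, relative 1.39, camera adjusted p = 0.00422, adjusted p = 0.208 with an estimated correlation). Polr1b rose from 0.603 ± 0.491 FPKM to 14.4 ± 3.52 FPKM and Gnl2 from 3.405 ± 0.0438 FPKM to 47.6 ± 1.92 FPKM. Proteasome subunits gave 29 risen and 7 not called, with 30 risen when adjusted over the list alone (median 3.28, relative 2.81, camera adjusted p = 1.07e-07, adjusted p = 0.195 with an estimated correlation). Oxidative phosphorylation subunits gave 43 risen and 34 not called, with 48 risen and 1 fallen when adjusted over the list alone (median 2.00, relative 1.53, camera adjusted p = 6.25e-08, adjusted p = 0.208 with an estimated correlation). S-phase genes gave 15 risen and 33 not called, with 14 risen when adjusted over the list alone (median 1.13, relative 0.66, camera adjusted p = 0.0463, adjusted p = 0.324 with an estimated correlation). The S-phase camera value was 0.169 after median-ratio rescaling and 0.0548 after quantile normalization (0.00269 to 0.324 over all alternatives). It was 0.0656 and 0.0669 without 8C replicate 1 and 2, 0.0565 without CX22 replicate 1, and 0.0546 and 0.138 without CX45 replicate 1 and 2.

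Maternal transcripts gave 28 fallen and 15 not called, with 29 fallen when adjusted over the list alone (median -2.60, relative -3.07, camera adjusted p = 2.24e-10, adjusted p = 0.292 with an estimated correlation). Among 2-cell-stage genes 4 rose (Tdpoz4, Pramel6, Pramel7 and Obox6) and 5 fell (Zscan4a, Zscan4b, Zscan4c, Zscan4d and Zscan4f), or 4 and 5 when adjusted over the list alone (median -0.47, relative -0.94, camera adjusted p = 0.306). Without CX45 replicate 2 camera passed downward at 0.00193 (0.00193 to 0.857 over all alternatives). Zscan4d fell from 128 ± 29.3 FPKM to 19.2 ± 10.5 FPKM. Among p53 targets 14 rose and 2 fell (Rrm2b and Rps27l), or 14 and 2 when adjusted over the list alone (median 1.24, relative 0.77, camera adjusted p = 0.0661). Without CX45 replicate 1 camera passed at 0.0419 (0.0116 to 0.568 over all alternatives). Btg2 rose from 0.525 ± 0.477 FPKM to 16.7 ± 6.63 FPKM and Cdkn1a from 14.99 ± 5.02 FPKM to 139 ± 29.3 FPKM. The SRY-box gene Sox15 was listed at 0 in CX22 and stood at 228 ± 23.6 FPKM in CX45. Chromatin architecture proteins (median 0.21, relative -0.26, -0.28 after median-ratio rescaling and -0.17 after quantile normalization), whose test was directed downward, and DNA methylation genes (mean -0.10, relative median -0.13, and a median of 0.34 that was -0.06 after median-ratio rescaling and -0.17 after quantile normalization) did not pass camera, nor did the lists not named above, with adjusted p between 0.0661 and 0.914. Blood markers had a median of 0.69 and a test directed downward. The call count was 2538 without 8C replicate 1, 2532 without 8C replicate 2, 2451 without CX45 replicate 1 and 2532 without CX45 replicate 2. Of 47 called genes followed, 9 lost their call without either 8C library, 4 and 6 without CX22 replicate 1 and 2, and 9 and 10 without CX45 replicate 1 and 2. Zscan4d was lost without CX22 replicate 1, CX22 replicate 2 or CX45 replicate 1.

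**Figure D1:**
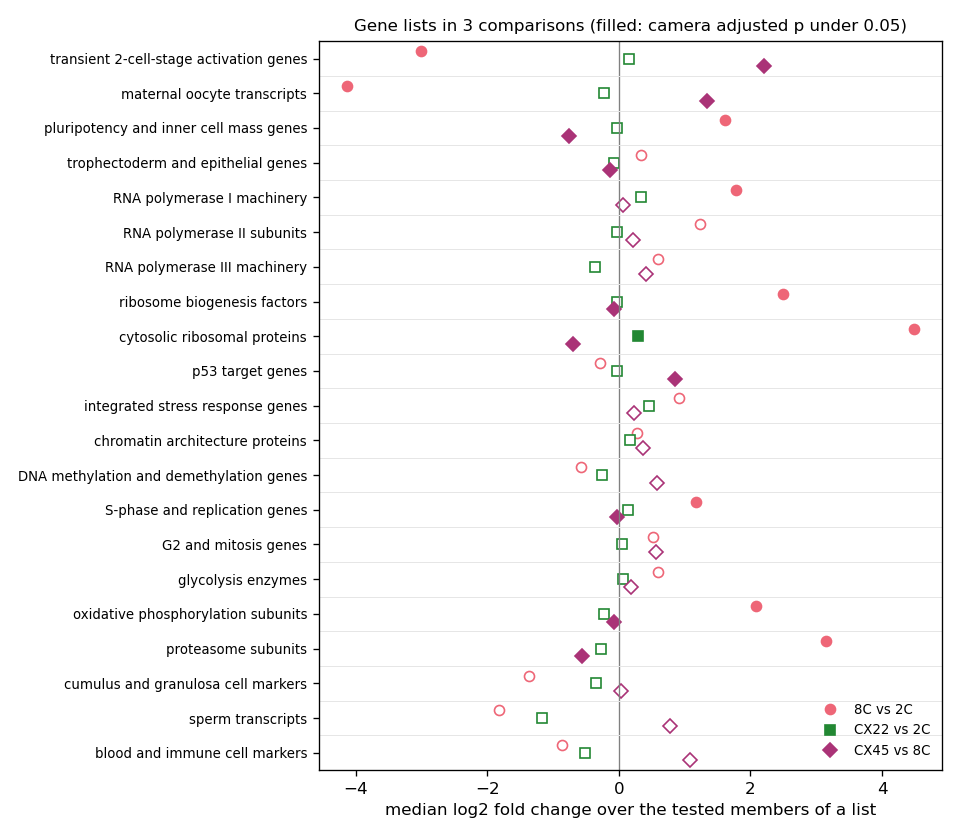
Median log2 fold change of each of the 21 gene lists (x axis) in 3 comparisons, 8C against 2C, CX22 against 2C and CX45 against 8C, with points filled where camera gave an adjusted p under 0.05 at the preset correlation. Cytosolic ribosomal proteins stood at 4.48 in 8C against 2C and maternal transcripts at -4.13, while the lists in CX22 against 2C lay nearer to 0.

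**Figure D2:**
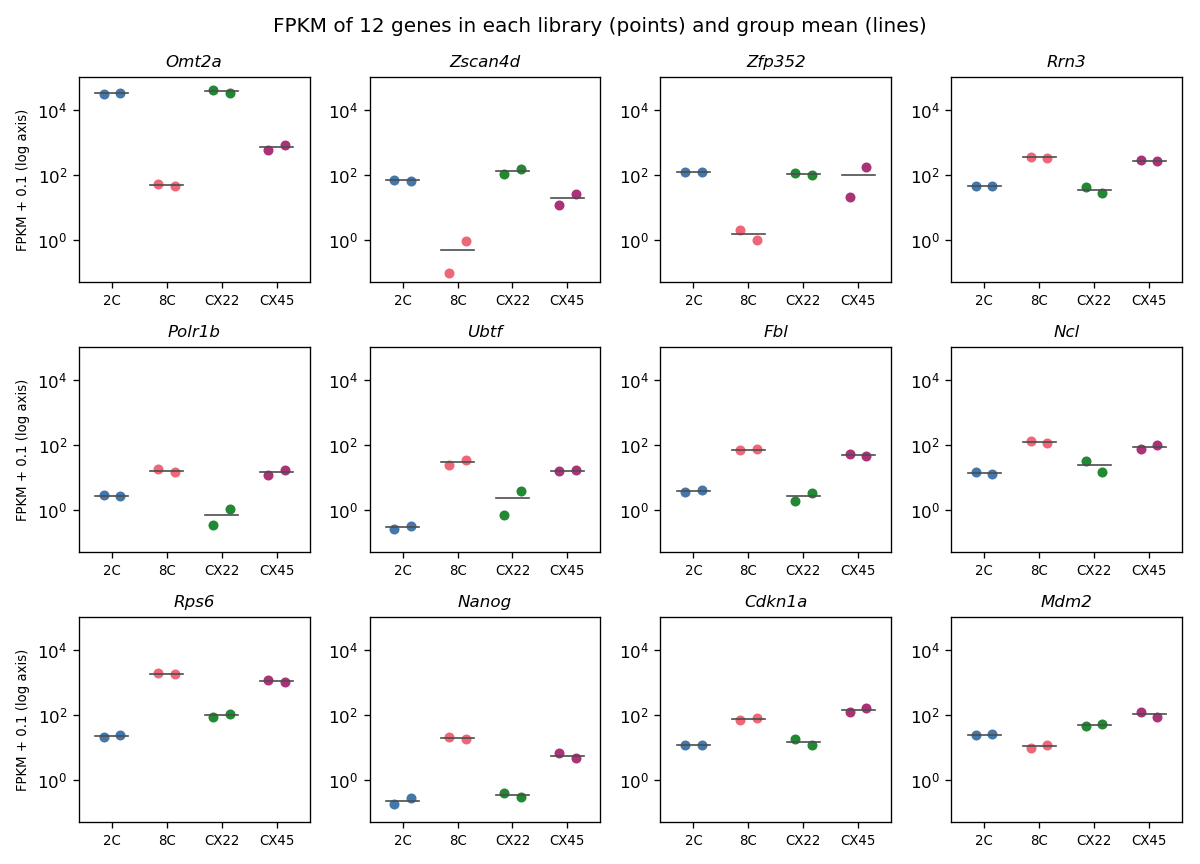
FPKM, with 0.1 added, of 12 named genes in each library on a log axis, with a point per library and a line at the group mean. Rrn3, Fbl and Rps6 stood higher in 8C and CX45 than in 2C and CX22, and Mdm2 was highest in CX45, at 106 ± 24.7 FPKM.

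Each CX library was placed on a scale from 2C (0) to 8C (1) by the genes that separated those stages, the selecting libraries never setting the levels. CX22 replicate 1 stood at 0.157 and replicate 2 at 0.104 (mean 0.130, SD 0.037, n = 2). CX45 replicate 1 stood at 0.777 and replicate 2 at 0.752 (mean 0.764, SD 0.018, n = 2). Between 4129 and 4289 genes entered, depending on the selecting pair. In CX45 the genes that rise from 2C to 8C gave 0.832 and 0.881, and those that fall gave 0.732 and 0.648. In CX22 the rising genes gave 0.106 and 0.098, and the falling genes 0.197 and 0.109. The selecting and the level-setting 2C library may not be independent, since their median difference was that of sampling noise. No test was made of these positions.

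**Figure D3:**
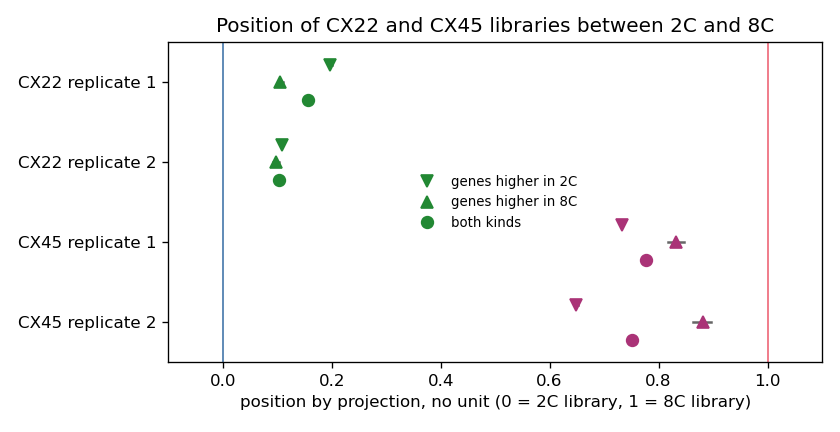
Position of each CX library between 2C (0) and 8C (1), for all selected genes and for rising and falling genes apart. The CX22 libraries sit at 0.157 and 0.104 and the CX45 libraries at 0.777 and 0.752.

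CX22 and CX45 were both compared with 2C: 34 genes rose in both, 326 fell in both and 12 went opposite ways, where independent sets of the same sizes would share 11.5 and 53.1. The correlation of the fold changes across genes was 0.389, against 0.665 in simulated groups without changes, and their covariance was 0.93, against 0.41. With 8C as the reference, 35 genes rose in both, 24 fell in both and 0 went opposite ways, where independent sets would share 10.9 and 5.1. The correlation was 0.580 against a simulated 0.498, and the covariance 1.30 against 0.20. Part of the excess in overlap and covariance may come from the samples that the comparisons share.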

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

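Averaging 2C, the most abundant entry per gene, and no genes listed at 0 in a whole group were chosen after seeing the data. Of the gene list results under alternatives, 2471 kept direction and side of the threshold, 58 passed it newly, 108 lost it and 3 turned. Of the named gene results, 5645 kept both, 830 lost the threshold, 75 passed it newly and 0 turned. In CX45 against 8C, limma called 184 genes with a pseudocount of 0.1, and 0 without a filter, after median-ratio rescaling, after quantile normalization, with the replicate term, in a fit of only those groups, and without genes listed at 0. The last 6 settings gave 2700, 2051, 1809, 2094, 3138 and 2129 genes at an unadjusted p under 0.05. Without the trend 2 genes were called there. In CX22 against 2C the count was 128 with a filter at 5 FPKM, where fewer genes are tested, and 249 after quantile normalization. It was 131 with the replicate term (4 higher and 127 lower), 60 without the trend, and 12 without genes listed at 0 in a group. The last removes 300 of the 462 called genes by construction and shifts the adjusted p of the others. In fits of only the compared groups, limma called 0 genes in CX45 against 2C (5121 at an unadjusted p under 0.05) and 2554 in CX45 against CX22. With the 8 libraries as separate samples, which adds a residual degree of freedom, the counts were 6697 in 8C against 2C, 1616 in CX22 against 2C, 6109 in CX45 against 2C and 1037 in CX45 against 8C. Leaving out each replicate in turn gave between 1417 and 5622 genes in 8C against 2C, 223 and 1113 in CX22 against 2C, 1871 and 5175 in CX22 against 8C, 1502 and 4928 in CX45 against 2C, 2451 and 4608 in CX45 against CX22, and 0 and 79 in CX45 against 8C, where the 0 stands beside 1238 or more at an unadjusted limma p under 0.05. The lone library of such a group was assumed to vary like the other groups. The stage position was 0.170 for CX22 and 0.746 for CX45 with a pseudocount of 0.1, and 0.790 for CX45 after quantile normalization. Oxidative phosphorylation subunits in CX45 against 8C turned upward under fry (median -0.081, adjusted p = 0.95) and after quantile normalization (median -0.075, camera adjusted p = 0.937, with 9.75e-05 to 0.95 over all alternatives). Chromatin architecture proteins in CX45 against CX22 turned upward under fry (median 0.214, adjusted p = 0.0468, with 0.0468 to 0.944 over all alternatives). Replicate deviations correlated across genes at 0.010, 0.105 and 0.040 among 8C, CX22 and CX45. Pairing of 2C was not checked. Apart from the settings whose construction is named, the cause was not tested. Depth limits the low end (3 fragments on 2 kb, at most 0.153 FPKM).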

Other observations

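The gene families and single genes in the next 2 paragraphs were chosen after their values were seen, and so were the tests on values of the single 2C sample, on listed zeros, on library scaling of the stage position, on a mixture as the whole account, on p53 targets with 2C above 8C, and on RNA of red blood cells. No list test is given for the families, since their genes were chosen for what they showed. Of 78 mitochondrial ribosomal protein genes, 45 rose from 2C to 8C and 1 fell (median log2 fold change 2.45). Of 55 translation initiation factor genes, 31 rose and 7 fell in that comparison (median 2.28). The TRiC chaperonin, which folds actin and tubulin, gave 6 risen genes of 8 (median 2.35). Mitochondrial import proteins gave 14 risen and 2 fallen of 23 (median 3.39). All 6 Tcl1 genes fell (median -7.14). Of 32 Oog and Pramel genes, 16 fell and 3 rose (median -2.28). These medians kept their sign after median-ratio rescaling and after quantile normalization. From CX22 to CX45, 5 of the 6 Tcl1 genes fell (median -4.89), and 49 of the 78 mitochondrial ribosomal protein genes rose (median 2.51), again with the same sign under both scalings.

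In CX45, 27 genes stood at 10 FPKM or more and at least 4 times above every 2C and 8C library in both replicates. Among them were Gadd45b, a stress-induced growth arrest gene (45.79 and 106.7 FPKM in CX45, between 4.011 and 9.53 in the 2C and 8C libraries), and Bcl2l11, which encodes the apoptosis activator Bim (53.54 and 43.09 FPKM, between 7.47 and 9.3 in 2C and 8C). The podoplanin gene Pdpn stood at 81.25 and 77.15 FPKM, against 13.08 to 17.77 in 2C and 8C and 6.644 and 6.195 in CX22. Omt2b was listed at 83520 FPKM in 2C replicate 1 and 99970 in CX22 replicate 1, and at 0 in 2C replicate 2 and CX22 replicate 2, in which its near-identical paralog Omt2a stood at 33190 and 33870.

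Limma called more genes lower (391) than higher (71) in CX22 against 2C. Noise of single libraries may add to this, which the counts leave open. Only in the 2C sample 89 genes stood high and 37 low, against 115 and 112 in CX22 replicate 1 and 103 and 58 in replicate 2. Of the 391 genes, 319 (81.6%) were also called lower in 8C and in CX45 against the same 2C sample, against 13% of all genes, 267 were listed at 0 in both CX22 libraries, and their median in 2C was 3.5 FPKM. Values peculiar to the single 2C sample and loss of transcripts from CX22 cannot be told apart here, since every comparison with 2C rests on that sample. Nor can listed zeros that are failed estimates be told apart from loss: among called genes without a listed 0 in any 2C or CX22 library 34 were lower and 30 higher, but the 267 genes stood at a median of 3.4 FPKM in 2C, where a loss would also end at 0. The 391 is therefore a count of listed values. The labels do not explain CX22, so no biological explanation was tested.

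The CX45 libraries lay between the stages, at 0.764 on average. The mean was 0.759 and 0.79 under both scalings, but shifts of rising and falling genes can cancel there, so scaling stays open. Whether a mixture of 2C and 8C material is the whole account cannot be told apart from expression of their own. A mixture would not give the 27 genes far above both stages in both CX45 replicates, of which 17 stood above 1 FPKM in every 2C and 8C library. Genes measured too low in those libraries could pass in both replicates, however. A CX45 and a CX22 library shared between 7 and 11 such genes, and the 27 was 2.45 times the most, under the 3 times needed. Whether those 7 to 11 reflect the shared libraries or expression common to CX22 and CX45 was not tested, so the bound may be too strict. This test replaced one on 18 genes called higher than both stages (8.9 expected of unrelated calls), which rested mostly on genes near the floor, and then a chance level from independent sets, which ignored the shared libraries. Whether a mixture in 1 share underlies part of the position cannot be told apart from stage-like expression: the 2C shares needed by falling genes (0.062 and 0.093) and rising genes (0.337 and 0.279) differed by -0.23 on average, but the quartiles of single genes were wide (0 to 0.177 and -0.003 to 0.604 in replicate 1).

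The p53 targets were higher in CX45 than in 8C (median 0.85). Library scaling cannot be told apart from a change of the list. Median-ratio rescaling and quantile normalization lowered the median to 0.41 (quartiles 0.05 to 1.79) and 0.55 (-0.10 to 1.74). The log2 fold change of Mdm2 (3.187) was then 2.705 and 2.718 and that of Trp53inp1 (3.708) 3.234 and 3.174, so their lost calls do not speak for scaling. The bound set before these values, a median over 0.3 with the camera call kept, was met (adjusted p = 0.000155 and 6.55e-05), but the lower quartile fell below 0 under quantile normalization, a condition added later. Camera compares a list with the other genes, so a shift of all genes hardly touches it. At an estimated correlation, where no list passed, adjusted p was 0.396 (lowest over all alternatives 2.79e-05). Levels carried over from 2C cannot be told apart from a change of their own, either for the 15 members with 2C at or below 8C or for the others. Of the 15, 12 were higher in CX45 (median 0.70, quartiles 0.20 to 0.79, a median reached by 0.38% of random lists), past the bound of 0.5 set before the value was seen. Under median-ratio rescaling and quantile normalization the median was 0.28 (quartiles -0.12 to 0.41) and 0.18 (-0.25 to 0.40), short of that bound. The random-list condition and the bound under both scalings were added after the 0.70 was seen. The 18 members with 2C above 8C had a median difference from 2C of 0.05, and 9 of them lay above 2C. The p53 list was not alone in standing higher: the blood and immune markers had a median of 1.08 with 0 of 6 called (camera adjusted p = 0.0592, 0.0309 and 0.0446 under the scalings, and 0.495 at an estimated correlation). Their summed FPKM was 308.5 and 376.9 in CX45 and 15.49 and 36.25 in 8C, mostly Hba-a1. It stood at 106.1 and 103.6 in 2C and 23.56 and 71.23 in CX22. RNA of red blood cells cannot be told apart from expression of Hba-a1 alone. Hbb genes summed to at most 0.11% of Hba-a1 in CX45, but 5 of 6 were listed at 0, perhaps failed estimates. RNA of other cells was not tested.

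A candidate explanation, with others open, is a p53 response in CX45. There 7 members (Mdm2, Ccng1, Btg2, Phlda3, Eda2r, Plk2 and Trp53) lay at least 1 log2 unit above both stages. In 10000 random lists the median was 2 and the 95th percentile 5, and 0.97% had as many. Under both scalings 4 and 6 did (95th percentile 3). The list was followed up for being high in CX45, so random lists cannot decide.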
